A study of Homo sapiens with 8 samples.

How the data were processed

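RNA was extracted from HT-144 cells as total RNA or as the polysomal fraction of a sucrose gradient, and libraries were sequenced with paired-end reads of 75 bp on an Illumina NextSeq instrument, per the labels' protocols. Per the submitters' processing notes, hg38 was the genome build and TopHat2 and Cufflinks 2.2.1 were used; the annotation and settings were not given in the sources used here. The authors deposited 1 table of FPKM values (fragment numbers relative to transcript length and to all mapped fragments) with 65535 isoform rows and 8 sample columns, per the file headers. With its header it has 65536 lines, the row limit of an older spreadsheet format, so further isoforms, if any, were not analysed here. Groups came from the sample labels and replicate numbers from the sample titles. Cufflinks divides reads between overlapping isoforms by a model, so values of isoforms of one gene are uncertain and depend on each other, and an exact 0 can be a failed estimate. FPKM also depends on all other transcripts in a library, so a few very abundant isoforms can shift the scale.

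In 21 rows all 8 columns held another kind of field (9 a genomic location, 7 a whole number, 2 a start site name, 3 a piece of a name), and these were left out. A row shifted by a single field would hold coverage instead of FPKM and would not have been recognised. In 5 cells a decimal comma was read as a point. Of the isoforms, 18413 were never above 0. Depth per library was unknown because Cufflinks FPKM holds no read counts, so no counting intervals were computed. No pair of libraries shared more than 0.00244% identical values, so each was counted as 1 replicate.

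Values were transformed as log2(FPKM + 1), without further scaling, and isoforms with at least 1 FPKM in at least 2 of the 8 libraries were tested (15531). Fold changes on this scale understate the change of low isoforms. A cell-means model over the 4 groups was fitted with limma 3.58.1 (R 4.3.3; eBayes with an intensity trend; 4 residual and 2.65 prior degrees of freedom), and p-values were adjusted by Benjamini and Hochberg within each of 5 comparisons, with a threshold of 0.05. The comparisons were DDX3X against control siRNA in polysomal and in total RNA, the difference between these changes, and polysomal against total RNA with each siRNA. The tests of these comparisons, most alternatives and the rule for named isoforms were chosen before the data were examined, apart from an addition to the rule and the alternatives and tests that the closing section names as added later. These choices were written for genes and were applied to isoforms.

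The rule named isoforms past the threshold, with no overlap of replicates between groups and a mean of at least 5 FPKM in the higher group, by size of change. It was met by 25 rising and 17 falling isoforms in polysomal RNA, 72 and 29 in total RNA, 1674 and 436 in polysomal against total RNA with control siRNA and 1708 and 703 with DDX3X siRNA. Because the files do not pair identifiers with gene names, at most 2 isoforms that rose and 2 that fell were named, those with the largest change in polysomal RNA. A minimum of 1 FPKM in all 8 libraries was added to this rule after values had been seen. Of 65535 identifiers, 1 matched the reference gene tables (uc001kfo.1, ACTA2-AS1, chromosome 10), and it was below the filter, at 0 to 0.0940 FPKM. DDX3X, MITF, the 27 fixed gene lists and 5′ UTR length and GC content were therefore not analysed here.

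The model code was tested on simulated data with the real isoforms' control means and moderated variances, among 15531 isoforms. Of 100 isoforms changed 2-fold, 57 were called in the polysomal contrast, 62 in the total RNA contrast and 16 in the contrast of ratios. Of 100 changed 4-fold, 96, 94 and 74 were called. Unchanged isoforms made up 4.97%, 8.24% and 6.25% of the calls. The simulated noise was normal and independent, so these shares can differ from those in the real libraries. Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, the libraries in the fit, the replicate number as a block and leaving out each library. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.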

Results

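RNA was sequenced from HT-144, an established human melanoma cell line, after siRNA against DDX3X or control siRNA. DDX3X is a DEAD-box RNA helicase known to act in translation initiation. For each siRNA, total RNA and polysomal RNA were sequenced, the latter being RNA bound by several ribosomes and recovered from a sucrose gradient. The 8 libraries formed 4 groups of 2. Values were FPKM per transcript isoform, so sequencing depth was unknown and no counting error could be given. Between 12786 and 13481 isoforms per library reached 1 FPKM. The first principal component, with 36.1% of the variance, separated polysomal from total RNA, and the second, with 15.6%, separated DDX3X from control siRNA. Pearson correlations of log2 values were 0.925 to 0.942 within a group, 0.905 to 0.938 between siRNAs in the same fraction and 0.864 to 0.899 between fractions. The deposited FPKM of one library summed to between 654252 (control polysomal replicate 2) and 5486860 (DDX3X polysomal replicate 1). Median-of-ratios factors, from tested isoforms above 0 in every library, ran from 0.949 (control total replicate 1) to 1.18 (DDX3X polysomal replicate 2). Most isoforms thus differed far less in scale than the sums. The files do not pair isoform identifiers with gene names, so DDX3X itself, MITF and the gene lists fixed beforehand were not analysed here, and the knockdown was not checked. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

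The design asked first which transcripts changed on polysomes with DDX3X siRNA. In polysomal RNA, 26 of 15531 tested isoforms rose and 19 fell at a limma adjusted p under 0.05. Isoform uc004bov.4 rose from 3.53 ± 0.375 to 14.0 ± 1.37 FPKM (SD, n = 2 per group), a log2 change of 1.73 ± 0.15 (SE) with a limma adjusted p = 0.0232. Isoform uc003skn.2 rose from 20.1 ± 0.344 to 54.1 ± 13.1 FPKM (SD, n = 2), a log2 change of 1.36 ± 0.16 (limma adjusted p = 0.0454). Isoform uc003upi.2 fell from 131 ± 18.8 to 55.3 ± 2.58 FPKM (SD, n = 2), a log2 change of -1.22 ± 0.14 (limma adjusted p = 0.0391). Isoform uc011baf.2 fell from 37.5 ± 6.59 to 15.7 ± 0.687 FPKM (SD, n = 2), a log2 change of -1.19 ± 0.13 (limma adjusted p = 0.0391).

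The called isoforms were mostly abundant. Of the 2484 isoforms with a mean of 20 FPKM or more, 15 rose and 15 fell, while the 5254 isoforms with a mean under 2 FPKM gave 1 of each. Among isoforms above 0 in every library, 25 rose and 11 fell, by at least 0.71 on the log2 scale and at most 2.54 up and -1.22 down. The other 9 called isoforms were listed at 0 in at least 1 library. Of these, 7 were listed at 0 in both DDX3X polysomal libraries, and 5 of the 7 were above 0 in all other libraries. An unadjusted p under 0.05 was reached by 2407 isoforms (1162 up, 1245 down), against 777 expected by chance. After quantile normalization 77 isoforms rose and 58 fell, and after median-of-ratios scaling 99 rose and 116 fell. With no filter 75 rose and 117 fell, and with no intensity trend or the replicate block 1 rose and 5 fell. Falls were also the majority without any one library. Rises stayed the majority at both other pseudocounts, at 5 FPKM or more, with robust eBayes and without isoforms listed at 0. The balance of rises and falls was therefore not stable. The DDX3X polysomal libraries differed from each other: replicate 1 listed 158 tested isoforms at 0 and replicate 2 listed 100, against 67 to 103 in the other libraries. Their median log2 values were 2.11 and 2.30. Whether this difference moved the counts was not tested. The count of 45 was not stable: it was 6 to 15 without any one of 7 libraries and 248 without DDX3X polysomal replicate 2. The 4 named isoforms kept their sign in all 19 alternative settings but passed the threshold in 10 (uc004bov.4), 6 (uc003skn.2), 9 (uc003upi.2) and 8 (uc011baf.2) of them.

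**Figure D1:**
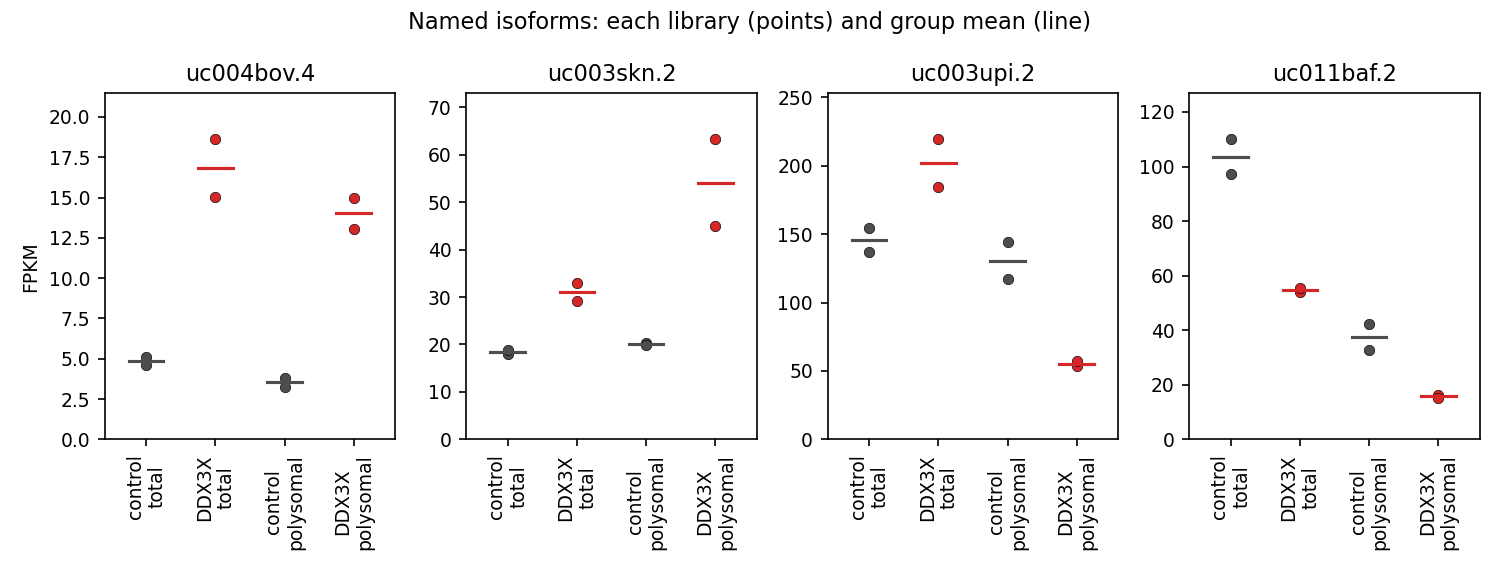
FPKM (linear axis from 0) of the 4 named isoforms in each library (points) and the mean of each group of 2 (lines), with control siRNA in grey and DDX3X siRNA in red. The values of uc003upi.2 with DDX3X siRNA lay at 202 FPKM in total RNA and 55.3 FPKM in polysomal RNA on average, against 146 and 131 FPKM with control siRNA.

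The same comparison in total RNA gave the change in RNA level. In total RNA, 87 isoforms rose and 33 fell with DDX3X siRNA (limma adjusted p under 0.05). Isoform uc004bov.4 rose from 4.87 ± 0.334 to 16.8 ± 2.58 FPKM (SD, n = 2), a log2 change of 1.60 ± 0.15 (limma adjusted p = 0.0195). Isoform uc011baf.2 fell from 104 ± 9.29 to 54.7 ± 1.03 FPKM (SD, n = 2), a log2 change of -0.91 ± 0.13 (limma adjusted p = 0.0489). Isoform uc003skn.2, at 18.3 ± 0.599 with control and 31.0 ± 2.68 FPKM with DDX3X siRNA (SD, n = 2), did not pass (log2 change 0.73, limma adjusted p = 0.0928). Nor did uc003upi.2, at 146 ± 12.5 and 202 ± 25.04 FPKM (SD, n = 2; log2 change 0.47, limma adjusted p = 0.147). Among isoforms above 0 in every library, 82 rose and 29 fell, by up to 4.03 and -2.02 on the log2 scale. The remaining 9 calls were isoforms above 0 in only 1 of the 4 groups.

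Rises made up 72.5% of the calls on the deposited values, 57.3% after quantile normalization (298 rose, 222 fell) and 53.3% after median-of-ratios scaling (248 rose, 217 fell). Both scalings centre the changes (median log2 change 0.04 on the deposited values and -0.01 after each), which in part sets this balance. Falls outnumbered rises among the calls when either DDX3X total RNA replicate was left out, and rises stayed the majority without any other single library. The majority of rises among the calls thus depended on both DDX3X total RNA libraries, though the lists without one of them were short. Of the 120 calls, 118 and 115 were also called after quantile normalization and median-of-ratios scaling. An unadjusted p under 0.05 was reached by 2856 isoforms (1747 up, 1109 down). The count of 120 fell to between 14 and 31 without any one of 6 libraries and reached 215 and 220 without DDX3X polysomal replicates 1 and 2. In total RNA uc004bov.4 and uc011baf.2 kept their sign in all 19 alternative settings and passed in 12 and 7 of them.

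The polysomal and total RNA changes were then set against each other. Their fold changes share no library, but their calls share each isoform's spread over all 8 libraries, so chance overlap exceeds that of independent lists. Of the called isoforms, 13 rose in both fractions and 3 fell in both, against 0.146 and 0.0404 expected for independent lists, and 0 were called in opposite directions. Fitted with limma on its own 4 libraries, each comparison made fewer calls (6 in polysomal RNA, 15 in total RNA), and 0 isoforms were called in both. For independent lists of these lengths 0.000644 rising and 0.00161 falling isoforms were expected in both. Lists this short leave little room for an overlap, so the 0 decides nothing. Across all tested isoforms, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.175 and a Spearman rho of 0.371. Over the 6427 isoforms with a mean of 5 FPKM or more and no value of 0, r was 0.489 and rho 0.554. Of the 26 isoforms that rose in polysomal RNA, 25 had a log2 change above 0 in total RNA, with a median of 0.73. Of the 19 that fell in polysomal RNA, 7 lay below 0 in total RNA. At an unadjusted p under 0.05 in polysomal RNA, 1059 of 1162 isoforms with a positive log2 change also had one in total RNA (91.1%), and 965 of 1245 with a negative log2 change also had one in total RNA (77.5%, median -0.27). Among the called isoforms, 1 that rose and 2 that fell were listed at 0 in all 4 total RNA libraries and had no change there. Without these the shares were 25 of 25 and 7 of 17 (Fisher's exact p = 1.32e-05, two-sided, with isoforms treated as independent). After quantile normalization they were 75 of 76 and 44 of 56 (Fisher's exact p = 0.000138, two-sided), and after refitting without isoforms listed at 0 they were 50 of 50 and 24 of 29. The share of isoforms that fell and lay below 0 in total RNA was not stable, at 0% to 69.8% without single libraries and 0 of 5 with no intensity trend or with the replicate block. As a set, the 26 isoforms were higher in total RNA with limma camera (adjusted p = 8.97e-18 over 4 sets with a preset correlation between isoforms, and adjusted p = 0.0271 with an estimated correlation of 0.172). For this set the preset correlation lay below the estimated one. The sets were also called with the shared spread over all 8 libraries, which can lower these p-values. The 19 isoforms did not pass (adjusted p = 0.127, and adjusted p = 0.173 with an estimated correlation). The 11 of them never listed at 0 were lower in total RNA (camera adjusted p = 0.0118), a call lost with an estimated correlation of -0.0549 (camera adjusted p = 0.0687). This estimate lay below the preset correlation, so the loss did not come from a higher correlation.

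**Figure D2:**
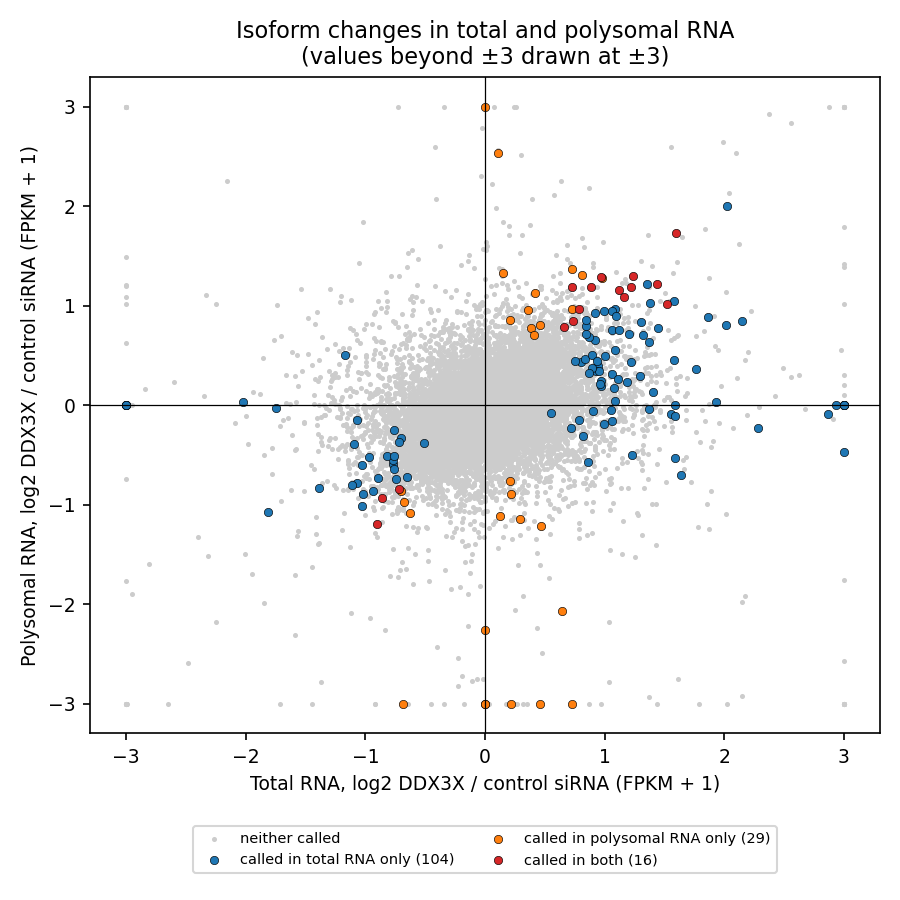
Log2 change with DDX3X siRNA of each of the 15531 tested isoforms in total RNA (x axis) and polysomal RNA (y axis), on the log2(FPKM + 1) scale, coloured by where limma called it. The 16 isoforms called in both fractions (red) lay in the quadrants where both changes had the same sign.

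Whether polysome association changed beyond RNA level was tested as the difference between the polysomal and total changes. The ratio of isoform uc003upi.2 differed by -1.69 ± 0.19 (SE) on the log2 scale with DDX3X siRNA, which did not pass (limma adjusted p = 0.0595); it passed in 3 of 18 alternative settings (limma adjusted p from 0.0203 to 0.229). Its polysomal mean was 131 FPKM against 146 FPKM in total RNA with control siRNA, and 55.3 against 202 FPKM with DDX3X siRNA (n = 2 each). The ratio of uc003skn.2 differed by 0.64 (limma adjusted p = 0.625), that of uc011baf.2 by -0.29 (adjusted p = 0.839) and that of uc004bov.4 by 0.13 (adjusted p = 0.963). Over the 15531 tested isoforms the ratio rose for 5 and fell for 13 (limma adjusted p under 0.05), and with no filter it rose for 79 and fell for 140 of 47101. Rises and falls were equal in number without DDX3X total replicate 2, and falls stayed the majority without any other single library. Of the 18 calls over the tested isoforms, 14 were listed at 0 in at least 1 library and 12 were above 0 in only 1 of the 4 groups. Of the 14, 9 were at 0 in all polysomal libraries of both siRNAs, so their difference came from total RNA alone and shows no shift on polysomes. The ratio of the 4 others fell, with log2 differences of -1.24 to -4.50. A limma fit without isoforms listed at 0 called 0 isoforms, with 1155 at an unadjusted p under 0.05. The adjusted p of the 4 were 0.110 to 0.130 in it, against 0.0288 to 0.0489 with all isoforms. On the deposited values 1147 isoforms reached an unadjusted p under 0.05, 334 up and 813 down, and after quantile normalization 618 did so up and 786 down. In simulated data this contrast called 16 of 100 isoforms changed 2-fold and 74 of 100 changed 4-fold. These were drawn from isoforms with a mean of at least 2 FPKM and no value of 0, so they do not cover calls listed at 0. The simulated noise was normal, independent and of moderated variance, so these shares can differ from those in the real libraries.

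Polysomal and total RNA were also compared within each siRNA. With control siRNA, 1976 isoforms were higher and 646 lower in polysomal RNA, and with DDX3X siRNA 1929 were higher and 1006 lower (limma adjusted p under 0.05). Isoform uc011baf.2 was lower in polysomal RNA with both, by a log2 difference of -1.45 ± 0.13 (SE) with control (limma adjusted p = 0.00191) and -1.74 ± 0.13 with DDX3X siRNA (limma adjusted p = 0.00121). Isoform uc003upi.2 was lower with DDX3X siRNA (-1.85 ± 0.14, limma adjusted p = 0.00116) and did not pass with control (-0.16, adjusted p = 0.471). Isoform uc003skn.2 was higher with DDX3X siRNA (0.76 ± 0.16, limma adjusted p = 0.0224) and did not pass with control (0.13, adjusted p = 0.638). For neither of the latter did the test of the difference between siRNAs pass, as given above. Isoform uc004bov.4 passed with neither (-0.37, limma adjusted p = 0.142, and -0.24, adjusted p = 0.317).

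Between the siRNAs, 1356 isoforms were higher in polysomal RNA in both (245 expected for independent lists), 428 were lower in both (41.8 expected) and 7 were called in opposite directions. These lists share the spread estimate, and with each comparison fitted on its own 4 libraries 695 were higher in both (101 expected), 193 lower in both (12.8 expected) and 0 opposite. Called differences over 4-fold were found for 50 higher and 51 lower isoforms with control siRNA and for 26 and 71 with DDX3X siRNA. Of these, 47 higher and 28 lower isoforms with control and 23 and 45 with DDX3X siRNA were never listed at 0. The log2 ratios of both siRNAs correlated across isoforms with r = 0.533 and rho = 0.635, and with r = 0.808 and rho = 0.815 at a mean of 5 FPKM or more and no value of 0. The median log2 difference of all isoforms with control siRNA was 0.12 on the deposited values and -0.01 after median-of-ratios scaling. That scaling gave 1536 higher and 1479 lower isoforms with control and 1833 and 1719 with DDX3X siRNA. Quantile normalization gave 1357 and 1339 with control and 1686 and 1575 with DDX3X siRNA. Higher isoforms then made up 50.3% and 51.7% of the calls, against 75.4% and 65.7% on the deposited values. The control siRNA count of 2622 fell to between 911 and 1311 without any one of the 4 libraries compared, and the DDX3X siRNA count of 2935 fell to 1129 and 1188 without total RNA replicates 1 and 2.

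**Figure D3:**
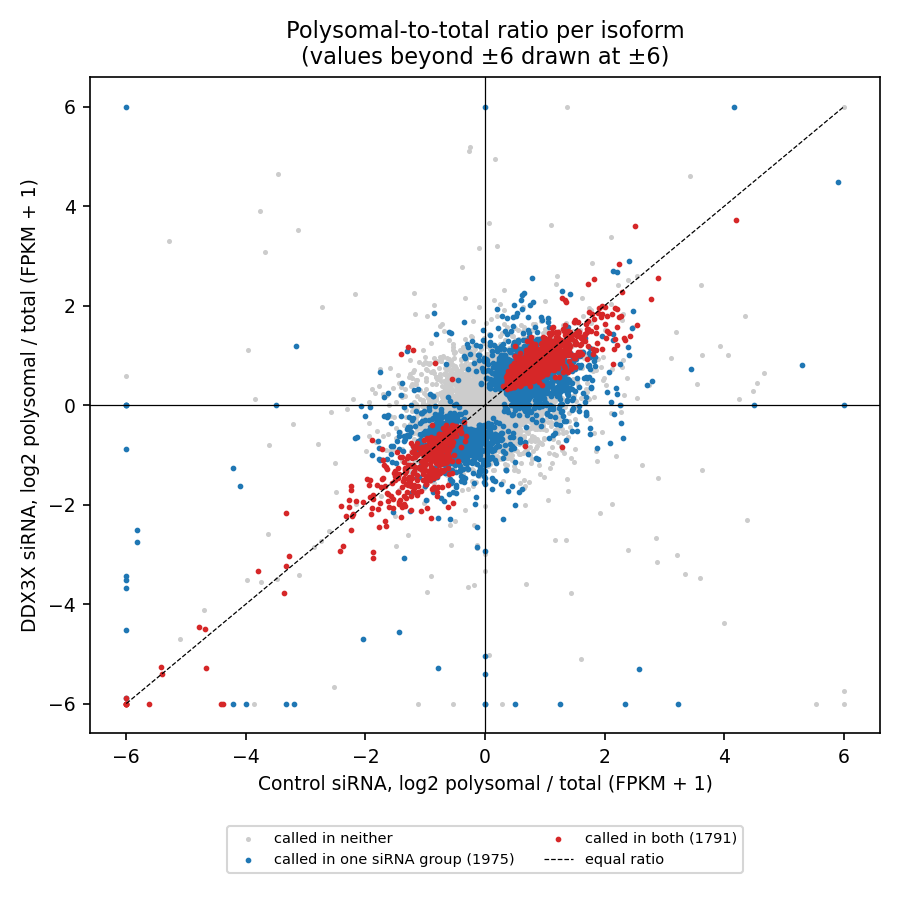
Log2 difference between polysomal and total RNA of each tested isoform with control siRNA (x axis) and DDX3X siRNA (y axis), on the log2(FPKM + 1) scale, with the dashed line marking equal differences. Isoforms called with both siRNAs (1791, red) lay mainly along that line, and 1975 were called with one.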

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

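The test of random detection was chosen after lists of called isoforms had been seen, the test without the highest isoforms and the test of carry-over after single values had been seen, and the 95% intervals used to read 3 of the tests and the quartiles used to read carry-over were set after their values had been seen.

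The changes with DDX3X siRNA in polysomal and total RNA differed, by the test of the difference itself, for 18 isoforms (limma adjusted p under 0.05), of which 5 had a higher and 13 a lower ratio. Of the 18, 14 were listed at 0 in at least 1 library, and 12 were above 0 in both libraries of 1 group and at 0 in the other 6 libraries. For 9 of the 14 all polysomal values were 0, so their difference came from total RNA alone. Chance detection in single libraries could give such isoforms: of 30 isoforms above 0 in exactly 2 libraries of the same fraction, 12 (40%, exact 95% interval 22.7 to 59.4) had both libraries from the same siRNA, against 33.3% by chance. These 12 were the called isoforms themselves, so every tested isoform above 0 only in both libraries of 1 group was called. The interval also allows a share well above chance, so an effect of DDX3X siRNA stays open. The 18 calls were not mainly of low isoforms. Their median absolute log2 difference was 5.61, and 4 with a higher and 7 with a lower ratio had a mean of 20 FPKM or more. Without isoforms listed at 0 a limma fit called 0 isoforms (1155 at an unadjusted p under 0.05). The 4 calls with no value of 0 (log2 differences -1.24 to -4.50) have the same estimates in any such fit by construction, so their loss (SE 0.123 to 0.491 with all isoforms and 0.129 to 0.472 in the refit, adjusted p 0.110 to 0.130) came from the variance moderation and the adjustment and says nothing about what gave them.

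Of the 19 isoforms that fell in polysomal RNA, 7 lay below 0 in total RNA (36.8%), while 25 of the 26 that rose lay above 0; at an unadjusted p under 0.05 the share was 965 of 1245 (77.5%), and 952 of 1217 (78.2%) among isoforms never listed at 0, so the low share belongs to the short list of calls. Values of 0 or the scaling between libraries could contribute. Without isoforms listed at 0, 6 of the 11 called isoforms lay below 0 (54.5%, exact 95% interval 23.4 to 83.3), and a refit without them gave 24 of 29 (82.8%). After quantile normalization 44 of 58 lay below 0 (75.9%, exact 95% interval 62.8 to 86.1). Both refits called a longer list, however. Robust eBayes, on the same values and scaling, gave 36 of 47 (76.6%), so a longer list can move the share by itself. The refits therefore cannot show whether values of 0 or the scaling gave the low share. Both intervals include the 75% set as the bound. For these called isoforms the explanations and an effect of DDX3X siRNA on polysome association cannot be told apart.

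The FPKM sums of the polysomal libraries were 5486860 and 2386820 with DDX3X siRNA and 896504 and 654252 with control siRNA, a ratio of means of 5.08. Carry-over of total RNA into the polysomal fraction of DDX3X siRNA cells would raise the polysomal ratio of isoforms depleted from polysomes by a median of 0.5 or more as set. The median differences of 68 and 67 such isoforms were -0.26 and -0.45 (upper 95% bounds 0.219 and 0.179, with isoforms treated as independent). These medians argue against carry-over of that size for these isoforms. Their quartiles ran from -2.78 to 1.29 and -3.15 to 1.82, so members went both ways, and smaller carry-over stays open. A few isoforms with very high FPKM may account for the sums: without the 10 highest isoforms the ratio of means was 1.05. They were chosen by their FPKM in these libraries, so leaving them out had to lower the highest sums. The top 10 of each library held 93.5% and 83.5% of the sum in DDX3X polysomal and 55.9% and 42.2% in control polysomal libraries. In total RNA, with sums of 2990410 to 3395220, they held 89.2% to 90.8%, so the test does not separate this explanation from carry-over. Of the 10 isoforms left out, 6 were tested and 1 rose in polysomal RNA with DDX3X siRNA (limma adjusted p = 1.67e-06). Of the 6, 4 were listed at 0 in at least 1 library, so a change with the siRNA stays open.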

How the results depend on the processing

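The fits without isoforms listed at 0, all values on isoforms that fell in polysomal RNA, the overlaps from separate fits and the shares without isoforms at 0 in all total RNA libraries were added after the data had been seen. Counts over 1.5 times away from the deposited-value count are given, and the cause was not tested except where fewer libraries or isoforms entered. The polysomal count (45) was 192 with no filter, 247 at 5 FPKM or more, 215 after median-of-ratios scaling, 135 after quantile normalization, 6 with no intensity trend, 105 with robust eBayes, 6 in only its 4 libraries, 79 without isoforms listed at 0 and 6 to 248 without single libraries. The total RNA count (120) was 198 at pseudocount 0.1, then, in the same order from no filter on, 205, 281, 465, 520, 34, 268, 15, 244 and 14 to 220. The ratio count (18) was 219 with no filter, 0 without isoforms listed at 0 (1155 at an unadjusted p under 0.05 in limma) and 13 to 25 without single libraries. Polysomal against total RNA with control siRNA (2622) gave 1668 with no filter and 911 to 3089 without single libraries (962 and 911 without control polysomal replicates 1 and 2, 1029 and 1311 without control total replicates 1 and 2). With DDX3X siRNA (2935) it gave 1785 with no filter, 1329 in only its 4 libraries and 1129 to 2564 without single libraries (1129 and 1188 without DDX3X total replicates 1 and 2). A group left with 1 library was assumed to vary like the others. The replicate numbers showed no pairing of the libraries over all tested isoforms (6 correlations of deviations, -0.08 to 0.08), which does not exclude pairing. With the replicate numbers as a block the counts were 6 (polysomal), 21 (total), 12 (ratio), 2171 (control) and 2449 (DDX3X siRNA). The Spearman correlation of the polysomal and total changes (0.371) was 0.327 and 0.421 at pseudocounts 0.1 and 5, 0.233 with no filter, 0.499 at 5 FPKM or more and 0.301 to 0.379 without single libraries. The share of isoforms that fell in polysomal RNA and lay below 0 in total RNA (36.8%) was 88.4% at 5 FPKM or more, 81.0% after median-of-ratios scaling, 75.9% after quantile normalization, 76.6% with robust eBayes, 82.8% without isoforms listed at 0, 0% with no intensity trend (0 of 5) and with the block (0 of 5), and 0% to 69.8% without single libraries. At pseudocount 5 that share was 56% (14 of 25). Rises made up 53.3% of the total RNA calls after median-of-ratios scaling and 57.3% after quantile normalization, both of which centre the changes, so that no explanation follows from these shares of rises. The ratio of uc004bov.4, not called, was -0.016 to 0.28 without single libraries (-0.016 without DDX3X total replicate 1) against 0.13. That of uc011baf.2, not called, was -0.46 to -0.11 without single libraries against -0.29, and that of uc003skn.2, not called, 0.39 to 0.88 against 0.64. DESeq2, for counts only, the small RNA filter, which needs gene symbols, the gene lists and the 5′ UTR test were not run. Depth was unknown, so its limits were not assessed.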

Other observations

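One hypothesis was that isoforms most associated with polysomes in control cells would lose association with DDX3X siRNA. With the control libraries split, so that the baseline and the change shared none of them, the rank correlation across isoforms was -0.0294 in one split and 0.0154 in the other, and neither reached the -0.1 set beforehand. Without the split it was -0.329, a value that includes the shared control libraries. In these libraries the hypothesis was therefore not borne out.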
